A study of Mus musculus with 32 samples.

How the data were processed

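Gene expression was measured in prefrontal cortex of mice from lines bred for opposite severity of ethanol withdrawal. The seizure-prone mice (WSP) and the seizure-resistant mice (WSR) each exist as 2 separately bred lines, so the series holds 4 breeding lines. Per the labels' protocols, mice breathed ethanol vapor for 72 hours after an ethanol injection of 1.5 g/kg, or 1.75 g/kg in the second WSP line. Controls stayed in air, and all mice received the alcohol dehydrogenase inhibitor pyrazole at 68.1 mg/kg. Tissue was taken after 21 days of abstinence. RNA of 2 animals was pooled for each array, and each group of sex, line and treatment held 4 arrays, which were 2 pools from each of 2 breeding lines. The 32 arrays formed 8 groups.

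The deposited array files gave 1 spot intensity and 1 background intensity per row, and per the labels the sample was labelled with 33P by reverse transcription from oligo-dT primers. The array platform, scanner and quantification software are not given in the sources used here. The background was a single value per array, between 6.96 and 30.3 intensity units, and it had not been subtracted from the spot intensity. Each array held 5355 spots, of which 4696 were gene spots, 192 were genomic DNA and 467 had unknown content. The authors also deposited a table of scores. Each score equalled 8 plus 2 times the standardised log2 intensity of the spot on its own array, to within 1.06e-06 on every array. The direction was therefore that of intensity, each array had been centred and scaled on its own, and the column medians lay between 7.29 and 8.55. Scores were present for gene spots above background and empty elsewhere, a rule that held for all 5355 spots of each array except Female WSP Air 4 (5354) and Female WSR Air 1 (5352). The table had 0 columns without a sample.

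Intensities were corrected with the normexp method with an offset of 50, moved to the log2 scale and quantile normalized over the gene spots. Gene spots at least 2 times background on at least 4 arrays were kept, which left 2084 probes. The offset compresses differences of dim probes, so the folds given here understate their change, and folds without background correction are given beside some called probes. A title of a gene stood on 1162 gene spots and on 454 of the kept probes, and the other 1630 kept probes were expressed sequence tags (ESTs, single reads of cDNA clones) or had no title. Names are those of the array files, and 0 of the clone accessions were found in the RefSeq gene table at hand.

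The model was fitted with limma 3.58.1 in R 4.3.3 with one mean per group, 24 residual degrees of freedom and an intensity trend in the moderation of variances. Contrasts of group means were tested with Benjamini-Hochberg adjustment over the 2084 probes, and an adjusted p under 0.05 is a call. There were 10 contrasts. The p-values measure the spread between pools, and pools of one breeding line are not independent samples of a selection phenotype. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Of 37 lists, 5 had at least 4 measured genes and were tested, namely inflammation and NF-kB signalling, heat shock proteins and ER chaperones, proteasome and ubiquitin, chromatin modifiers, and actin, tubulin and cell cycle genes. Symbols of list members were assigned by hand from the titles; by then counts of called probes had been seen, but no result of a single gene or list. A gene with several probes was taken at the brightest one. Figures were drawn with matplotlib 3.10.9.

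The groups, contrasts, lists, naming rule and most other settings were fixed before the data were examined. The rule named, per contrast, the 12 called titled probes with the highest and the 12 with the lowest moderated t. It filled each direction to 6 by the smallest p where fewer passed, and these are given as not passing. It added up to 4 members of any list that passed or held a called member, the sex-linked genes, and the 2 most intense measured members of each list of another cell type or neighbouring tissue. The text describes a subset of these, chosen with their values in view, and names outside it are marked where they appear. The result of 1 marker gene is not reported here. The design had asked for probes with 1 gene symbol; the files give titles, so titles were used.

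Other settings fixed in advance were median scaling, cyclic loess, no background correction, no filter, only probes above the median brightness, the authors' table, no intensity trend, array weights, other thresholds, leaving out replicates, blocks on breeding line and pool, the arrays of one comparison alone, single breeding lines, and other partings of the breeding lines. Counts of called probes under several normalizations and the principal components had already been seen when further settings were added and when the tests of technical and biological explanations were set down. The added ones set each array on its own mean and spread, left out the Female WSP EtOH array of replicate 1 or the Female WSR Air array of replicate 1, or used a component of the control and unknown spots as a covariate. The same counts had been seen when the tests of other splits of the arrays were set down, though no split had been run.

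Replicate numbers in the labels stand for breeding line and pool. The headers of Male WSP EtOH replicate 3 and Male WSR Air replicate 2 give another pool than the titles, and those of female WSR give none. The titles were used, so the pool is uncertain there, which bears on the block on pool, the correlations of same numbers and the replicates left out. Air and ethanol arrays of one breeding line share ancestry, and the labels pair them by line. Deviations of air and ethanol arrays from their group means were compared over all kept probes. Arrays with the same number correlated with a mean r of 0.12 in female WSP, -0.0014 in female WSR, 0.0039 in male WSP and 0.25 in male WSR. For arrays of the same breeding line the mean r was 0.24 in male WSR.

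The step that makes calls was tested on simulated data with 200 changed probes among 2084. In the comparison of ethanol with air in female WSP, 54.5% of 1.3-fold, 84.5% of 1.5-fold and 99.0% of 2-fold changes were recovered. Over both sexes and lines, 92.5% of 1.3-fold changes were recovered. The simulated noise was independent between probes and between arrays, and the folds were planted on the scale that the offset compresses. With fewer changed probes the adjustment is stricter. These shares therefore do not show that the real comparisons would have found changes of that size.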

Results

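The study asked how genetic background shapes gene expression in the prefrontal cortex during abstinence after chronic ethanol. Expression was measured on 32 single-channel arrays, with 4 arrays for each combination of sex, selected line (WSP or WSR) and treatment (ethanol vapor or air), at 21 days after exposure. Each array carried RNA pooled from 2 mice. The number of arrays limits the precision of every value.

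Array brightness followed line in males, where WSP and WSR arrays did not overlap, while the 2 lines overlapped in females. Male WSR arrays had 1682 to 2040 of 4696 gene spots at 2 times background or more, and male WSP arrays had 518 to 604. Female WSP arrays had 588 to 1428 such spots and female WSR arrays 783 to 1095. The SD of log2 intensity within an array averaged 2.06 in male WSR, 1.04 in male WSP, 1.51 in female WSP and 1.58 in female WSR. The first principal component of the normalized values held 47.4% of the variance, and all 8 male WSR arrays lay apart from the other arrays on it.

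**Figure D1:**
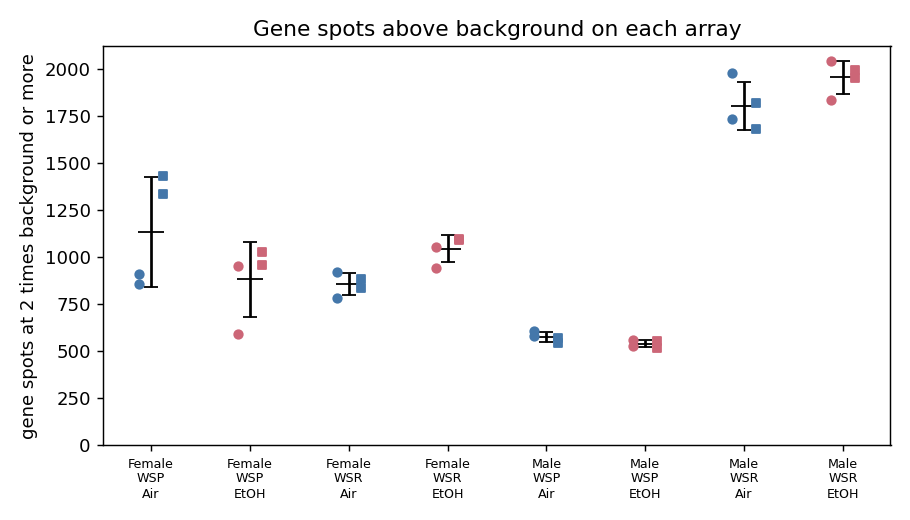
Number of gene spots at 2 times background or more (vertical axis, spots) on each array, by group (horizontal axis). Air is blue and ethanol red, circles are replicates 1 and 2, squares replicates 3 and 4, and black bars are the group mean ± SD of 4 arrays; male WSR arrays had 1682 to 2040 such spots and male WSP arrays 518 to 604.

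Gene titles could not be checked against the transcripts, and every gene named here is the title of a spot. Transcripts that brain makes in quantity were not bright. The 32 spots titled as cytosolic ribosomal proteins, tubulins, respiratory chain or ATP synthase subunits or elongation factor 1 had a mean brightness percentile of 45.7, and 2 of them lay above the 90th. The Y-linked gene Eif2s3y was expected only in males. Its spot was 2 times background on 4 arrays, and it was higher in females by a log2 difference of 0.20 ± 0.042 (SE, adjusted p = 0.00015, 16 arrays per sex, 14 female arrays above the male mean). That spot therefore did not serve as a check of the sex labels.

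In female WSP mice, 8 probes differed between ethanol and air, 5 higher and 3 lower after ethanol. The spot titled G protein alpha 13 (Gna13), a subunit that carries signals from membrane receptors, was higher by a log2 difference of 0.87 ± 0.18 (SE, adjusted p = 0.023, 4 of 4 ethanol arrays above the air mean), which was 2.87-fold without background correction on a spot that reached 2 times background on 10 of 32 arrays. In air, replicate 2 lay at 7.03 and the other arrays between 5.95 and 6.02. Drg2, a GTP-binding protein, was lower, with a log2 difference of -0.59 ± 0.13 (adjusted p = 0.031, 4 of 4 arrays below the air mean, 1.57-fold without background correction). Its mean was 8.98 ± 0.30 (SD, n = 4) after ethanol and 9.57 ± 0.25 in air. An anonymous clone, ESTM671070, was higher by 0.99 ± 0.22 (adjusted p = 0.035), although its spot reached 2 times background on only 6 of 32 arrays, with ethanol replicate 4 at 6.18 and the others between 6.94 and 7.07. The other 5 called probes carried only EST titles; among them, chosen after its values were seen, an EST described as similar to the transcription inhibitor HEXIM1 was higher by 0.58 ± 0.12 (adjusted p = 0.023).

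Further genes in female WSP did not pass. Rbx1, a subunit of ubiquitin ligases, had a log2 difference of 0.35 (adjusted p = 0.096), with ethanol replicate 1 apart from the others at 8.66, and selenocysteine lyase had 0.59 (adjusted p = 0.097); under median scaling both turned, to -0.33 and -0.14. Endoglin (Eng), a co-receptor for TGF-beta in endothelial cells, had 0.57, galectin 1 had -0.63 and apoptosis inhibitor 5 had -0.74, each with an adjusted p of 0.11. For Eng, air replicate 2 lay at 6.76, above the other air arrays. None of the 5 gene lists passed, and none of 9 marker spots of neurons, glia, vessels, choroid plexus or blood passed. The count of 8 rested on few arrays: it was 0 without replicate 3, 24 without replicate 1, 34 without replicate 4 and 30 without the single ethanol array of replicate 1. The authors' table gave 51 calls, a block on breeding line and pool 15 and array weights 2. Under median scaling 148 probes were lower and 0 higher, with a median shift of all probes of -0.12, and with only the 8 arrays compared in the fit the count was 0.

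**Figure D2:**
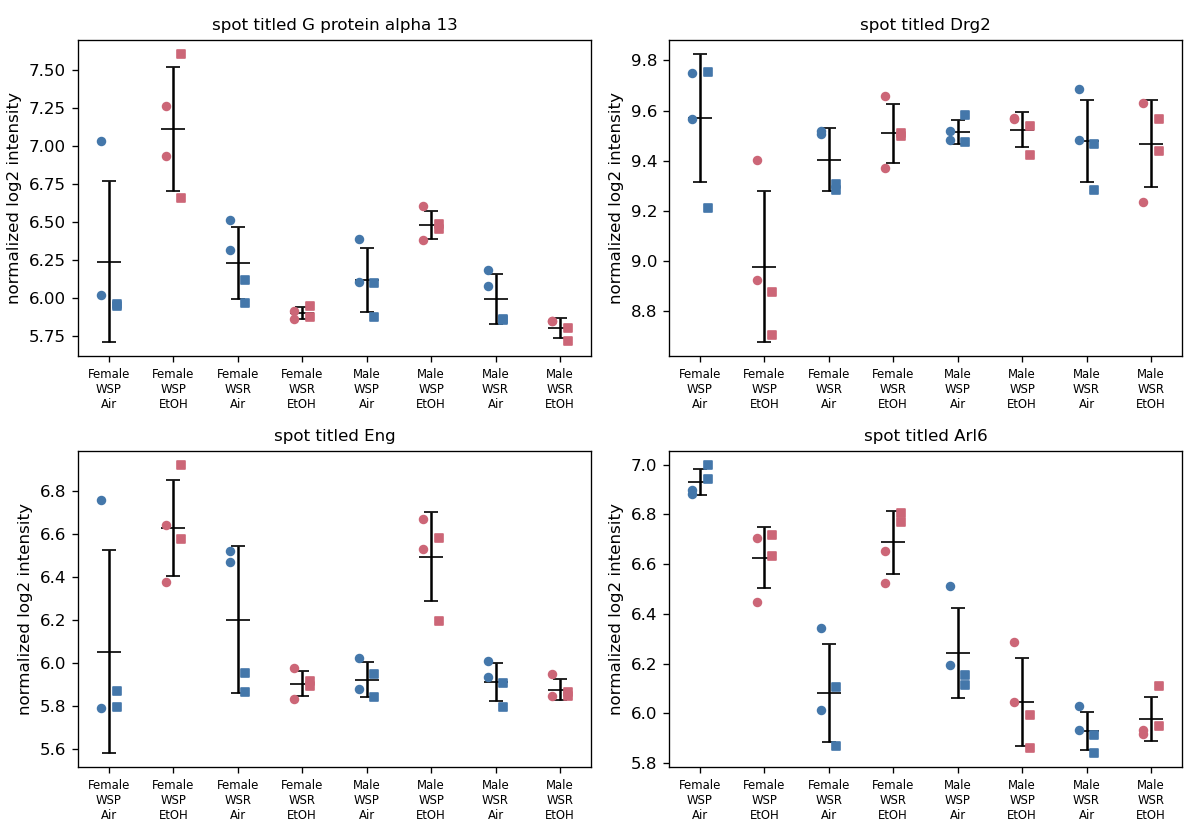
Normalized log2 intensity (vertical axes) of the spots titled G protein alpha 13, Drg2, Eng and Arl6 on each array, by group (horizontal axes). Air is blue and ethanol red, circles are replicates 1 and 2, squares replicates 3 and 4, and black bars are the mean ± SD of 4 arrays; Drg2 averaged 8.98 in female WSP after ethanol and 9.57 in air, and Arl6 averaged 6.69 in female WSR after ethanol and 6.08 in air.

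In female WSR mice, 1 probe passed. The spot titled Arl6, a small GTPase of the ADP-ribosylation factor family, was higher after ethanol by a log2 difference of 0.60 ± 0.11 (SE, adjusted p = 0.0089, 4 of 4 arrays above the air mean), or 2.16-fold without background correction. This spot reached 2 times background on 18 of 32 arrays. Its mean was 6.69 ± 0.13 (SD, n = 4) after ethanol and 6.08 ± 0.20 in air. Psmd4, a ubiquitin receptor of the proteasome, had a log2 difference of 0.60 (adjusted p = 0.21) and did not pass, nor did the scaffold protein Dlg4 at 0.39, the glutathione enzyme Ggt1 at 0.48, cyclin D3 (Ccnd3) at 0.51 and the decarboxylase Ddc at -0.25. All 4 measured members of the proteasome list had differences above 0, none was called over all probes, and 1 was called when adjusted over the list alone. Camera gave that list an adjusted p of 0.094, while fry gave 5.47e-05. Fry tests the average change of the members without comparing them with other probes. All 4 members of the actin, tubulin and cell cycle list were also above 0, with 2 called when adjusted over the list alone, and camera gave 0.094 and fry 0.0098. No marker spot passed. With the breeding line as a block 2 probes were called. With a block on breeding line and pool 0 were (Arl6 adjusted p = 0.16), while the limma fit without a block had 270 at an unadjusted p under 0.05. With median scaling (median shift 0.10) or cyclic loess 0 were, and the authors' table gave 27. Without replicate 1 the count was 2, both higher, and without replicate 2 it was 0. Without replicate 3 it was 1 and without replicate 4 it was 2, all of them lower, so Arl6 was no longer called without replicate 2 (adjusted p = 0.17), replicate 3 (0.050) or replicate 4 (0.12).

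In male WSP mice, 1 probe passed, a spot with no title that was named only after its values were seen (EST clone AI428279). It was higher after ethanol by a log2 difference of 0.56 ± 0.11 (SE, adjusted p = 0.022). Among titled spots, gamma-fibrinogen had 0.62 (adjusted p = 0.11), TGFB inducible early growth response had 0.40 (adjusted p = 0.16) and Eng had 0.57 (adjusted p = 0.17). Brp44l, whose spot reached 2 times background on male WSR arrays alone, had -0.34 (adjusted p = 0.11). No list and no marker spot passed; the inflammation list had 0 of 5 members above 0 (camera adjusted p = 0.26). In the authors' table, where the heat shock list alone could be tested, that list was lower (adjusted p = 0.0033). The count was 5 without background correction, 7 with array weights, and 0 with median scaling, cyclic loess or the authors' table, against 176 probes at an unadjusted p under 0.05 in limma. It was 2 without the Female WSR Air array of replicate 1. Without replicate 1 the count was 8, without replicate 2 it was 2, and without replicate 3 or replicate 4 it was 0.

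In male WSR mice, limma called 0 probes, and 64 had an unadjusted p under 0.05. Glycine N-methyltransferase had a log2 difference of 0.39 (adjusted p = 0.67), MAD homolog 3, a signal carrier of the TGF-beta pathway, had 0.48 (adjusted p = 0.79) and Rras had 0.14 (adjusted p = 0.80). The list of heat shock proteins and ER chaperones rose as a group in camera (adjusted p = 0.030, 6 of 7 members above 0, median log2 difference 0.080). The call was lost with an estimated correlation, where the adjusted p = 0.077. Fry gave 0.18. None of its 7 members passed over all probes and none when adjusted over the list alone; Hspb8, a small heat shock protein, had 0.13 ± 0.046, and Hspe1 had 0.16 ± 0.15, which was -0.048 in the first WSR breeding line alone. With median scaling, which moved the median of all probes by 0.18, 143 probes were called, 141 of them higher, and the list no longer passed (adjusted p = 0.15). It also missed the threshold with no filter (0.16), in the authors' table (0.86) and without replicate 1 (0.074), replicate 2 (0.085) or replicate 4 (0.10). No marker spot passed. Cyclic loess called 48 probes, array weights 31, and the breeding line as a block 2.

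Over both sexes and lines, 0 probes passed in limma, and 98 had an unadjusted p under 0.05. Rbx1 had a log2 difference of 0.15 ± 0.046, with 15 of 16 ethanol arrays above the air mean, and Ggt1 had 0.22 ± 0.071, with 13 of 16 arrays above it; both had an adjusted p of 0.86. The authors' table gave 8 calls, all lower. The response to ethanol also showed 0 calls for a difference between the sexes, with 122 probes at an unadjusted p under 0.05; DXHXS6673E had the difference 0.28 (adjusted p = 0.56), with male WSR ethanol replicate 4 apart from the others at 5.81. No list passed in camera in either comparison. Over both sexes and lines fry gave an adjusted p of 0.040 for the heat shock list, the proteasome list and the actin, tubulin and cell cycle list. Members above 0 were 6 of 7, 4 of 4 and 4 of 4. Over both sexes and lines the actin, tubulin and cell cycle list passed as higher under median scaling (adjusted p = 0.048), and for the sex difference the heat shock list passed as higher in the authors' table (adjusted p = 0.014). The authors' table gave 14 calls for the sex difference.

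The ethanol response differed between WSP and WSR at 5 probes. The log2 difference of WSP minus that of WSR was -0.58 ± 0.11 for Arl6 (SE, adjusted p = 0.018), 0.88 ± 0.18 for G protein alpha 13 (adjusted p = 0.036), 0.74 ± 0.16 for Eng (adjusted p = 0.040) and 1.02 ± 0.22 for ESTM671070 (adjusted p = 0.040). For Arl6 the group means went from 6.93 in air to 6.63 after ethanol in female WSP and from 6.24 to 6.05 in male WSP, but from 6.08 to 6.69 in female WSR and from 5.93 to 5.98 in male WSR. For G protein alpha 13 they went from 6.24 to 7.11 and from 6.12 to 6.48 in female and male WSP, and from 6.23 to 5.90 in female WSR. The means of Eng and ESTM671070 were higher after ethanol in WSP of both sexes. The spots of G protein alpha 13, Eng and ESTM671070 reached 2 times background on only 10, 11 and 6 of 32 arrays, so their lower means in WSR are not read as a direction. Those WSR means still enter the differences and calls of these 3 spots. The fifth was the untitled clone AI428279, at 0.47 ± 0.11 (adjusted p = 0.046). Eng was also the vessel marker and the 1 of 9 marker spots called here, so a different share of vessel tissue was not ruled out for it. MAD homolog 3 (-0.55), Hsd17b1 (-0.47) and Psma1 (-0.41) did not pass, each with an adjusted p of 0.16. No list passed in camera; for the proteasome list camera gave 0.34 and fry 0.00029. In ESTM671070, Female WSR Air replicate 1 lay at 7.54 and the others between 5.80 and 5.99. The count was 0 with cyclic loess, 0 with a block on breeding line and pool, 2 without replicate 2, 0 without replicate 3, 0 without replicate 4 and 3 without that Female WSR Air array, against 262 probes at an unadjusted p under 0.05 in limma. The authors' table gave 73, 41 of them higher, and array weights 12; median scaling, which shifted the median by -0.20, gave 570 calls, of which 562 were lower.

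Between the lines in air, 830 probes differed, 339 higher and 491 lower in WSP, and over both treatments 1134 differed, 467 higher and 667 lower. Median scaling, which shifted the medians by -0.34 and -0.42, gave 61 higher and 1487 lower in air and 31 higher and 1718 lower over both treatments; the authors' table gave 394 higher and 945 lower over both. GDP dissociation inhibitor 3, which holds Rab GTPases in their inactive state, was higher in WSP over both treatments by a log2 difference of 0.64 ± 0.066 (SE, adjusted p = 2.47e-09, 16 of 16 WSP arrays above the WSR mean). Lysosomal membrane glycoprotein 1 was higher by 0.52, acid ceramidase by 0.55 and the polarity protein Pals1 by 0.37, each in 16 of 16 arrays. All 4 of these spots varied more among WSR than WSP arrays, with an SD of 0.71 against 0.26 for GDP dissociation inhibitor 3. For GDP dissociation inhibitor 3, female arrays of both lines averaged 8.60 ± 0.17 (SD), and Male WSP EtOH arrays lay between 8.10 and 8.35. The WSR mean was 7.86, so the low values of this spot lay mainly in male WSR arrays. Whether the male WSR arrays alone give the 4 differences was not tested. Under median scaling all 4 of these directions turned, to -1.16, -0.99, -1.25 and -1.19, so their direction depends on how the arrays are scaled; in the authors' table the glycoprotein (-0.027) and Pals1 (-0.38) turned as well. A UDP-galactose transporter was lower in WSP by -0.38 ± 0.030 (adjusted p = 3.95e-11), and Rps6ka2, a kinase downstream of MAP kinases, had -0.34, Mapk13 -0.46 and retinoblastoma 1 -0.43. Of the 667 probes lower in WSP, 302 reached 2 times background on male WSR arrays alone, as did 8 of the 467 higher ones. The spots of the transporter, Rps6ka2 and retinoblastoma 1 each reached it on 8 arrays.

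In air alone, Arl6 was higher in WSP by 0.58 ± 0.077 (adjusted p = 2.66e-06, 8 of 8 arrays) and Psmd4 by 0.61 (adjusted p = 0.00015). The same air arrays enter the line difference of the ethanol response of Arl6, so its 2 results are not independent. After ethanol the Arl6 means were 6.63 in female WSP, 6.69 in female WSR, 6.05 in male WSP and 5.98 in male WSR. Pyrroline-5-carboxylate synthetase (-0.30), CD82 antigen (-0.39) and lymphocyte protein tyrosine kinase (-0.52) were lower, and each of these 3 spots reached 2 times background only on the 8 male WSR arrays. The same held for 236 of the 491 probes lower in WSP in air and 5 of the 339 higher ones, which reached it on male WSR arrays alone. Among chromatin modifiers, 4 of 6 measured members were lower over both treatments and 0 higher, or 5 when adjusted over the list alone, with Ezh2 at -0.22, on a spot 2 times background on male WSR arrays alone, and Cbx5 at -0.29; camera gave the list an adjusted p of 0.21. In the actin, tubulin and cell cycle list 2 of 4 members were called, both lower (camera 0.21). Over both treatments fry, which does not compare members with other probes, gave 2.09e-07 for the chromatin list and 6.02e-07 for the actin list. It gave 0.00079 for the heat shock list, 0.0026 for the proteasome list and 0.039 for the inflammation list. In this comparison 54.4% of all kept probes were called. Low fry values and counts of called members therefore do not by themselves set a list apart. Of the heat shock list 5 of 7 were called, 1 of them higher (camera 0.55), with Hspe1 at -0.43; of the proteasome list 4 of 4, 2 of them higher (camera 0.96); and of the inflammation list 3 of 5, 2 of them higher (camera 0.55). Of marker spots, the astrocyte gene Glul was higher in WSP in air by 0.30 (adjusted p = 0.027), and -0.99 under median scaling. Over both treatments Eng was higher in WSP by 0.30 ± 0.079 (SE, adjusted p = 0.0020) and hemoglobin Hba-a1 by 0.19 (adjusted p = 0.0092), while the choroid plexus gene Ttr was lower at -0.16 (adjusted p = 0.044). In air alone none of them passed: Eng had -0.069 (adjusted p = 0.66), Hba-a1 0.17 (0.13) and Ttr 0.0061 (0.97). The directions over both treatments also depended on scaling: under median scaling Eng had -0.035 and Hba-a1 -1.38, and in the authors' table Ttr had 0.37. Within females 252 probes differed between the lines, and within males 1216. Across the 2084 probes, which are not independent, the line difference in females correlated with that in males at r = 0.030. In males the lines differed in array brightness without overlap, so line and array run cannot be told apart there.

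Between the sexes, 1234 probes differed, 495 higher and 739 lower in females. Median scaling gave 268 higher and 954 lower, while 679 were higher and 565 lower in the authors' table. GDP dissociation inhibitor 3 was higher in females by 0.84 ± 0.066 (SE, adjusted p = 3.57e-11, 16 of 16 arrays above the male mean). Its SD was 0.17 in females and 0.62 in males. Male WSR arrays lie on the lower side of this comparison and of that between the lines. Female arrays of both lines averaged 8.60 on this spot and WSP arrays of both sexes 8.50 (SD 0.26), against 7.76 in males. Both differences of this spot may therefore come mainly from the male WSR arrays, which was not tested. Proteasome subunit Psmd7 was higher by 0.60, nucleophosmin 1 by 0.50 and the NF-kB subunit Rela by 0.51. The UDP-galactose transporter was lower at -0.39, as were LIM and SH3 protein 1 at -0.36 and the glucocorticoid-induced gene Tsc22d3 at -0.40, all 3 on spots that reached 2 times background on male WSR arrays alone. Of the 739 probes lower in females, 337 reached 2 times background on male WSR arrays alone. Within WSP 389 probes differed between the sexes and within WSR 1254. The sex difference in WSP correlated with that in WSR at r = 0.14 across probes. No list passed in camera. Of inflammation genes 4 of 5 were called, 3 of them higher in females, and of heat shock genes 6 of 7, 2 of them higher. The counts were the same when adjusted over each list alone. Since 59.2% of all kept probes were called, such counts and low fry values do not by themselves set a list apart. Fry gave an adjusted p of 0.00032 for the inflammation list, 0.00010 for the heat shock list and 1.90e-05 for the chromatin list. For the actin, tubulin and cell cycle list it gave 7.72e-06, and for the proteasome list 0.56. The astrocyte markers Glul and Dio2 went opposite ways, at 0.17 (adjusted p = 0.049) and -0.31 (adjusted p = 9.13e-05), though Glul turned to -0.059 under median scaling.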

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

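The tests of the gene titles, the test of breeding line on the female component, the splits within breeding lines, and the split tests for the 3 comparisons with 0 calls were chosen after the results they measure had been seen.

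The ethanol response differed between the lines at 5 probes by the test of the difference itself. Because the second WSP line had the higher injected dose, line and dose are partly mixed in it. The differences were -0.58 for Arl6, 0.47 for the untitled clone AI428279, 0.74 for Eng, 1.02 for ESTM671070 and 0.88 for G protein alpha 13 on the log2 scale. Of 100 splits of the arrays within sex and line, only the real one gave 5 calls, and the highest other gave 2; the same held when treatment was moved only within breeding lines. At 1 of 100 splits, chance in how treatment fell among the pools is unlikely as the source of that count, but not excluded. The share was not corrected for the 10 contrasts, and it does not extend to the 4 breeding lines. These splits were fitted without a block; with a block on breeding line and pool limma called 0 probes, and 262 had an unadjusted p under 0.05 without it. The 4 titled spots kept their direction in the other settings run for them, but the calls held in only some: of 18 settings, 13 called Arl6 (adjusted p from 0.0019 to 0.23), 12 G protein alpha 13 (0.0029 to 0.23), 10 Eng (0.0054 to 0.25) and 9 ESTM671070 (0.0017 to 0.29).

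For ethanol against air within one sex and line, chance could not be excluded by splits that disregard the breeding line. In female WSP 12 of 35 splits of the 8 arrays called at least the 8 probes of the real one, and the highest other called 54. That is several times the real count and points to a structure of these arrays other than treatment. In female WSR 4 of 35 splits gave at least 1 call, with a highest other of 4, and in male WSP 16 of 35 did, with a highest other of 4. With 0 real calls the comparison with other splits could not come out otherwise, and all were as large in male WSR (35 of 35, highest other 27), over both sexes and lines (100 of 100, highest other 1) and for the sex difference (100 of 100, highest other 2). Splits that keep 2 arrays of each breeding line on either side number 18, too few for a share under 0.05. The highest other among them was 9 in female WSP, 1 in female WSR, 4 in male WSP and 3 in male WSR, against 8, 1, 1 and 0 in the real one. With the real one included, 2 of the 18 were as large in female WSP, 2 in female WSR, 9 in male WSP and 18 in male WSR. The splits with 54 calls in female WSP, 4 in female WSR and 27 in male WSR mixed the breeding lines unevenly. For the line and sex contrasts the real split alone was as large, 1 of 100 in each, against a highest other of 424 for lines in air, 690 for lines over both treatments and 679 for sex. These splits move pools, so chance among pools is unlikely at 1 of 100, but they say nothing of chance among the 4 breeding lines. A split also mixes arrays across a large difference between strata, and splits with so many calls point to structure in the arrays.

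Many calls separated lines and sexes. Dim probes at the floor of the narrow arrays are not the whole source, since 46.0% of probes at 2 times background on all 32 arrays were also called between WSP and WSR. Of these 218 bright called probes 142 were higher in WSP, against 467 of all 1134 called, so direction varied with brightness. Whether the unequal range of the arrays gives the calls of bright probes was not tested. A run of male WSR arrays that stands apart remains a candidate explanation: the line difference in females correlated with that in males at only 0.030 across probes, although a line difference specific to one sex would give the same. Selection for withdrawal severity stays open, because in female arrays the real parting of the breeding lines called 137 probes and the other partings 0, but 3 partings are too few to exclude chance. Line and array run cannot be told apart in males, whose lines differed in brightness without overlap, while in females brightness overlapped.

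The female arrays parted into 2 clusters on the third component (4.17% of variance), with 1 of 4 Female WSP Air, 2 of 4 Female WSP EtOH, 3 of 4 Female WSR Air and 0 of 4 Female WSR EtOH arrays on the positive side. A difference between arrays or hybridisations was tested by the correlation with the first component of the control and unknown spots, whose size was 0.18 (Pearson -0.18, permutation p = 0.50; Spearman -0.25, permutation p = 0.35; Pearson -0.38 without the 2 farthest of 16 arrays). That lies under the bound set against this explanation, but its interval runs from -0.62 to 0.35 and scores in clusters make a correlation a poor test, so it stays open. Breeding line accounted for 0.38 of the variance, between the bounds set for and against a difference of animals, and these cannot be told apart. The component overlaps with treatment in female WSR.

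Titles of transcripts abundant in brain lay on dim spots. A shifted or mirrored layout is argued against: of 399 other layouts tried, none brought the mean percentile of these titles above 64.2, against 45.7 as given, and the best one scattered the genomic DNA spots (SD 24.4 percentile points against 4.21). Only shifts of up to 2 positions, with or without mirroring, were tried. Clones that are not the named gene are a candidate explanation, since the 21 pairs of spots that share a title lay 29.96 percentile points apart on average, against 27.7 for random pairs (0.702 of random draws at or below). The Eif2s3y spot was higher in females, against its sex. The criterion set for this explanation had also asked for such a reversal. Only this spot met that part, and it reached 2 times background on only 4 arrays. With its direction left out, the criterion does not decide. A join of names to spots that is wrong in another way was not tested. No biological explanation was tested for this pattern.

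Single arrays stood far from the other 3 of their group in 18 of 315 tests of named genes and of spots above background, where chance gives about 15.8. The gap divided by the range was 0.93 for G protein alpha 13 and 0.92 for Eng in Female WSP Air, in both on replicate 2, which lay above the others, and 0.95 for Dio2 on replicate 4. In Female WSP EtOH it was 0.86 for ESTM671070 and 0.92 for Rbx1. Female WSR Air had 0.89 for ESTM671070, 0.87 for Rbx1, 0.92 for Ccnd3, 0.90 for Hba-a1 and 0.85 for acid ceramidase. Male WSP EtOH had 0.93 for Brp44l, 0.94 for bisphosphate 3'-nucleotidase and 0.93 for GDP dissociation inhibitor 3, all on replicate 1, and Male WSP Air had 0.89 for CD82 antigen. Male WSR EtOH had 0.85 for ESTM671070, 0.84 for Arl6 and 0.93 for DXHXS6673E, and Male WSR Air had 0.96 for Rbx1.

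Spots of unknown content entered no comparison. Of 467 such spots, 56 were at 2 times background or more on all 32 arrays.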

How the results depend on the processing

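The scale of each array by its own mean and spread, the single arrays left out and the control-spot covariate were chosen after seeing the data. Counts for ethanol against air are given in the order female WSP, female WSR, male WSP and male WSR, where the main counts were 8, 1, 1 and 0, followed by the line difference of the response (5). Median scaling gave 148, 0, 0, 143 and 570, cyclic loess 21, 0, 0, 48 and 0, and array weights 2, 1, 7, 31 and 12. The authors' table gave 51, 27, 0, 0 and 73, with 27 higher of 51, 4 higher of 27 and 41 higher of 73, plus 8 over both sexes and lines and 14 for the sex difference, all lower. Each array on its own mean and spread gave 55 (26 higher), 0, 0, 0 and 52 (23 higher), with 411 higher and 1073 lower for lines over both treatments, and the control-spot covariate 5, 1, 1, 0 and 2. Without background correction male WSP had 5, and with no filter 6, where the line difference had 2. At an unadjusted p under 0.05 with 1.3-fold the counts were 100, 84, 39, 14 and 80, 23 for the sex difference, 247 for lines in air, 261 for lines over both treatments and 300 for sex. At an adjusted p under 0.1 female WSP had 14. With only the 8 arrays compared, the counts were 0 in all 4 comparisons. Single breeding lines gave 14 and 45 in female WSP, 22 and 4 in female WSR, and 0 and 9 in male WSP. The selection replicate block gave 7, 2, 1, 2 and 5, and the replicate block of selection replicate and pool gave 15, 0, 1, 0 and 0; the blocks moved no other count by over 1.5 times. Leaving out replicates gave 0 to 34, 0 to 2, 0 to 8, 0 to 0 and 0 to 6; the line difference was 3 without the Female WSR Air array of replicate 1. Lines in air ranged from 631 to 848, lines over both treatments from 977 to 1155 and sex from 1094 to 1271. Median scaling gave 1548 for lines in air, with 61 higher and 1487 lower, and 1749 over both treatments, with 31 higher and 1718 lower; for sex it gave 1222, with 268 higher. The other partings of the breeding lines gave 0 and 0 for both line contrasts, and the breeding line as a random block gave 774, 1053 and 1246. Gene list calls were 1 in the main test, 0 with an estimated correlation, 18 with fry, 1 with median scaling, 0 with no filter, 2 in the authors' table and 0 to 1 when replicates were left out. Except as stated, the cause was not tested; single lines and single comparisons hold fewer arrays. Batches of slide or scan were not run, since the array files used here give none.

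Median scaling turned Rbx1 (-0.33) and selenocysteine lyase (-0.14) in female WSP, and in the line contrasts GDP dissociation inhibitor 3 (-0.73 in air, -1.16 over both treatments), aldolase A (-0.016), lysosomal membrane glycoprotein 1 (-0.99), acid ceramidase (-1.25), Pals1 (-1.19), Eng (-0.035), Hba-a1 (-1.38) and Glul (-0.99 in air), with Glul at -0.059 between the sexes. The authors' table and each array on its own mean and spread turned lysosomal membrane glycoprotein 1 (-0.027), Pals1 (-0.38) and Ttr (0.37). Hspe1 in male WSR was -0.048 in breeding line WSR-1 alone. For the 8 called results of named genes in ethanol contrasts, 93 of 156 values kept direction and call, and the others kept direction alone. For the 40 results in line and sex contrasts, 660 of 717 did, 41 lost the call and 16 turned. Few spots exceeded 2 times background in male WSP, which limits what can be seen there.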

Other observations

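The gene lists had few measured members, since few stood on the array by title and fewer passed the filter on dim probes. Little can therefore be said of most of the signalling that the design set out to cover. GABA-A receptor subunits, microglia, striatal and olfactory bulb markers, neurotrophic factors and candidate genes of mapped withdrawal loci had 0 measured members. Before the filter, neurotrophic factors had 6 members on the array, microglia markers 4 and the candidate genes 2. The single measured member of the glucocorticoid list, Tsc22d3, was lower in females by a log2 difference of -0.40 ± 0.038 (SE, 16 arrays per sex), and its spot reached 2 times background on the 8 male WSR arrays alone.

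Called probes went the same way in both breeding lines, which the call itself favours: 8 of 8 in female WSP, 1 of 1 in female WSR and 1 of 1 in male WSP. Over all kept probes the ethanol differences of the breeding lines correlated at 0.14 in female WSP, 0.095 in female WSR, 0.21 in male WSP and 0.0039 in male WSR, across probes that are not independent.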
